A study of Mus musculus with 11 samples.

How the data were processed

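The series holds RNA sequencing of CD8 T cells sorted from the spleens of C57BL/6 mice. The labels give 3 naive libraries (CD44lo CD8 T cells), 4 CD45RBhi NP396+ memory libraries and 4 CD45RBlo NP396+ memory libraries. For the memory groups they state infection with 200000 pfu of LCMV Armstrong, a virus that causes an acute infection, and sorting with an NP396 tetramer on days 42 to 45 after it (week 6), to a purity above 99%. The labels of the naive libraries repeat this text. They also carry a time entry of 6 to 8 weeks, and its meaning, such as mouse age, is not stated. Whether the naive and memory mice differed in age is therefore not known here. The tetramer binds T cells specific for 1 peptide of the viral nucleoprotein, and CD45RB is a splice form of CD45 that contains exon B. The labels do not state that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

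The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene, with 1 column per library and no normalization. The submitters' processing notes name SAMtools, featureCounts and DESeq2 and the builds mm10 and GRCm38, with no versions. The aligner, the annotation release and the strandedness are not given in the sources used here. The table has 52636 genes, of which 6417 carry no symbol and 171 share a symbol with another gene. A count in any library was present for 24292 genes. All 11 libraries were used, and no library was left out. Total counts per library ran from 18.0 to 23.2 M, so 3 counts, the limit that a count of 0 allows, correspond to 0.130 to 0.166 CPM (counts scaled to a common library total) in a library. Intervals and limits of this kind cover counting error only. Replicate libraries were checked for duplicates. None of 15 pairs was identical, and their chi-square per degree of freedom ran from 9.43 to 84.7.

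Genes were kept with edgeR's filterByExpr (minimum count 10), which left 13735 genes holding at least 99.9% of each library's counts. Libraries were scaled by TMM. Group means were fitted to all libraries in 1 model without covariates, and groups were compared with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 18.7%. Levels are means of CPM ± SD with n = 3 naive, n = 4 CD45RBhi and n = 4 CD45RBlo libraries, and log2 fold changes are given ± SE. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures with matplotlib 3.10.9. Gene positions, lengths and GC contents came from GENCODE M21 on GRCm38, which holds 52403 of the identifiers. It need not be the annotation that the reads were counted on.

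The comparisons, the tests, 28 gene lists with 970 entries, the rule for named genes and most of the other settings tried were chosen before the data were examined. The rule named, for each comparison, up to 10 genes with the largest change in each direction among genes that passed, averaged at least 10 CPM over all 11 libraries and did not overlap between the groups. Pseudo-genes, clone names, receptor segments, immunoglobulin and ribosomal protein genes were left out of that part. It added up to 4 members of each list by p, and a fixed set of sort and memory markers whatever their p. For the paired fit, added after the data were seen, the same direction in all 4 pairs took the place of no overlap, so its genes may overlap between the groups and lie below 10 CPM in memory libraries. Genes named outside these rules, such as Cd74, Ighm, Cpne7 and single V segments, were chosen after their values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 84 tests (28 lists in 3 comparisons), and again with an estimated correlation. Rotation tests (fry) were run beside them. They ask whether a list's genes move on balance 1 way and do not compare the list with other genes. Members were counted with p adjusted over all genes tested and with p adjusted over the list alone.

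Replicate numbers are shared between the groups, so it was checked whether they pair the libraries. The deviations of same-numbered CD45RBhi and CD45RBlo libraries from their group means correlated at 0.191 to 0.452 across genes. Differently numbered ones reached at most 0.0284, and 8 of 8 memory libraries correlated best with their own number. The pairing therefore comes from the data and not from the labels. Memory and naive libraries of the same number correlated at -0.101 to 0.0565 and were not taken as pairs. A fit of the 8 memory libraries with the replicate number as a block was added after the data were seen. It tested 12637 genes with a coefficient of variation of 9.88%, and its lists were adjusted over 28 tests.

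The position of each library on the naive-to-memory axis was the mean signed log2 CPM (prior count 2) over the genes called between naive and the mean of both memory groups. Positions, and the diversity and largest share of T-cell receptor V segments, were compared by exact two-sided permutation tests. The overlap of both memory-naive comparisons was set beside 20 simulated data sets of unchanged groups that shared the naive libraries.

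Alternatives tried were RLE scaling, library size only, no filter, a filter of 10 CPM, DESeq2, limma-voom, the replicate block, a test against a 1.5-fold change (glmTreat), a fit of only the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were fits with pair terms for the memory libraries, every alternative to the paired fit, same-numbered differences in V segment diversity, the counts of each list under each scaling, and a loess correction of each memory library for gene length and GC content before limma-trend.

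The calls were tested on simulated data with 50 changed genes at each fold. Every 4-fold change in a gene of at least 10 CPM was called in each comparison, while 78% of all 4-fold changes, 60% of 2-fold and 40% of 1.5-fold changes were called between the memory groups without pairing. That set held no deviations shared by same-numbered libraries, unlike the real memory libraries. In 1 simulated set with such deviations, a fit of the 8 memory libraries without the block called 76%, 60% and 18%, and 0 of its 77 calls were false. The bound on recovery was first set over all genes and was restricted to genes of at least 10 CPM after the first run missed it, since every missed 4-fold change lay below 10 CPM. In 10 further simulated sets, 62 of 947 calls without pairing (6.55%) and 102 of 1326 calls with pairing (7.69%) were false, both above the nominal 5%. The sets without pairing again held no shared deviations, so their 6.55% need not hold for the real memory libraries. With no change simulated, the paired fit called 24 genes over 10 sets. The noise of each gene was drawn independently in these sets, so the shares need not hold for real genes that move together. In 1 simulated set DESeq2 gave 26 false calls among 132 (19.7%).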

Results

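Gene expression was measured in naive CD8 T cells (3 libraries) and in CD45RBhi and CD45RBlo NP396+ memory CD8 T cells (4 libraries each) from mouse spleen. Total counts averaged 19.1 ± 1.41 M in naive, 21.2 ± 1.38 M in CD45RBhi and 20.1 ± 1.78 M in CD45RBlo libraries (SD). Over the 1000 most variable genes, component 1 held 87.1% of the variance and parted naive from memory libraries. Component 2 held 3.31% and parted replicate numbers within memory: replicate 1 of CD45RBhi lay at 22.9 and replicate 1 of CD45RBlo at 23.3. Component 3 held 2.01%.

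**Figure D1:**
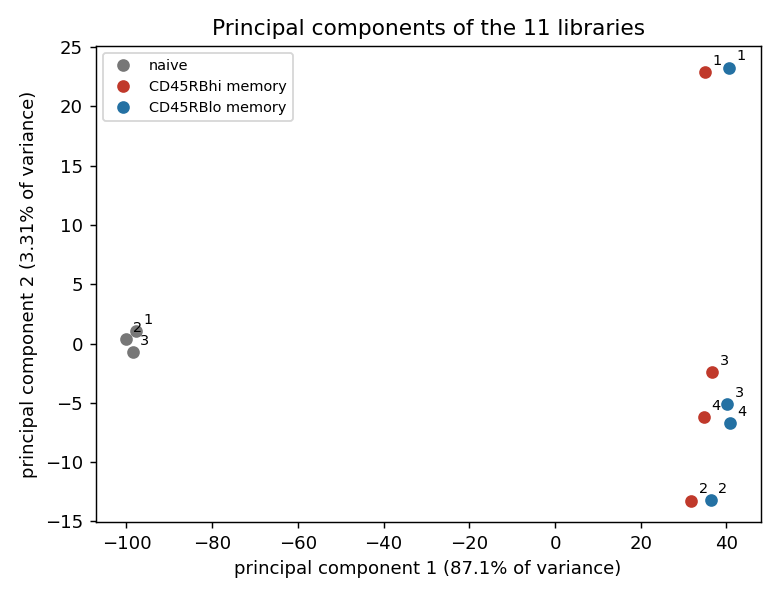
Principal component scores of the 11 libraries over 1000 genes, with the share of variance on each axis and 1 point per library, coloured by group. Component 1 (87.1%) parts naive from memory libraries, and same-numbered CD45RBhi and CD45RBlo libraries lie near each other on component 2.

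The genes behind the sort were read first. Cd44, the adhesion receptor that marks antigen-experienced T cells, was at 14.6 ± 2.87 CPM in naive, 256 ± 57.4 in CD45RBhi and 220 ± 38.7 in CD45RBlo libraries. It rose by 4.12 and 3.91 log2 units against naive (adjusted p = 1.53e-08 and 2.07e-08). In the paired fit Cd44 was higher in CD45RBhi than in CD45RBlo by 0.21 log2 units (adjusted p = 0.0436, 4 of 4 pairs). That call was lost when single pairs were left out. Ptprc, which encodes CD45, was at 2981 ± 222 CPM in CD45RBhi and 2976 ± 189 in CD45RBlo libraries (naive 2627 ± 26.8). Its log2 fold change between the memory groups was 0.00 ± 0.0672, adjusted p = 0.998, and counts per gene do not tell whether exon B was included. Hnrnpll, a splicing factor that represses CD45 variable exons, rose from 38.5 ± 3.34 CPM in naive to 68.6 ± 4.76 in CD45RBhi (log2 fold change 0.83, adjusted p = 4.32e-05). It reached 75.1 ± 7.73 in CD45RBlo libraries (0.96, adjusted p = 1.12e-05), and its value between the memory groups was -0.13 ± 0.0958 (adjusted p = 0.734). Cd8a fell by 0.43 on the log2 scale in both memory groups, from 1323 ± 89.1 CPM in naive to 986 ± 56.9 and 980 ± 70.6. Cd4 had 0 to 9 counts per library and was not tested.

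The comparison of CD45RBhi with CD45RBlo memory asks how memory cells that differ in CD45RB differ in expression. Satb1, a chromatin organizer of T cells, was at 338 ± 19.6 CPM in CD45RBhi and 178.5 ± 17.3 in CD45RBlo libraries (log2 fold change 0.92 ± 0.0808, adjusted p = 0.000758). Il7r, the receptor chain for the survival cytokine IL-7, was at 1196 ± 45.0 and 770 ± 39.9 CPM (0.63 ± 0.065, adjusted p = 0.00147). Sh3bp5 (0.71), Plac8 (0.71), Ms4a4c (0.69), Pdlim1 (0.54) and Ly6e (0.50) were also higher in CD45RBhi. Timp2, a metalloproteinase inhibitor, was lower at 11.9 ± 3.27 against 32.7 ± 3.64 CPM (-1.46 ± 0.165, adjusted p = 0.00338). Matk, a kinase that inhibits Src kinases, was at 11.3 ± 2.05 and 27.0 ± 5.22 CPM (-1.25 ± 0.16, adjusted p = 0.00833). Jup, which encodes the junction protein plakoglobin, was at 12.2 ± 1.11 and 25.8 ± 1.45 CPM (-1.08 ± 0.109, adjusted p = 0.00147). Each of these genes kept every CD45RBhi library on 1 side of every CD45RBlo library, which the rule for naming them required. On GRCm38, Satb1 (ENSMUSG00000023927) lies on chromosome 17 from 51736187 to 51833290 and Il7r (ENSMUSG00000003882) on chromosome 15 from 9505788 to 9530176. Timp2 (ENSMUSG00000017466) lies on chromosome 11 from 118301069 to 118355740, Matk (ENSMUSG00000004933) on chromosome 10 from 81252935 to 81263365, and Jup (ENSMUSG00000001552) on chromosome 11 from 100368958 to 100397763. In all, 17 of 13735 genes passed without pairing, 11 higher and 6 lower in CD45RBhi, and 1236 had an unadjusted p under 0.05. Leaving out 1 library gave 6 to 15 genes: 6 without CD45RBhi replicate 3 or 4, 9 without CD45RBlo replicate 1, and 7 without CD45RBlo replicate 3 or 4. DESeq2 called 144 genes, the fit of the memory groups alone 4, and the test against a 1.5-fold change 0.

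With the replicate number as a block over the 8 memory libraries, 707 of 12637 genes passed, 318 higher and 389 lower in CD45RBhi, and all 17 genes called without pairing were among them. In simulated data 7.69% of calls of this fit were false, but the noise of each simulated gene was drawn independently. Real genes can move together, so this share is not the error rate of the 707 calls. Ccr7, the chemokine receptor for lymph node entry, rose by 0.43 (adjusted p = 0.0024, 0.62 unpaired) and the transcription factor Tcf7 by 0.36 (0.00198, 0.176 unpaired). Myc (0.75), Bcl2 (0.41), Cnr2 (1.54), Cotl1 (1.22), Treml2 (0.82) and Eya2 (0.75) were also higher. Cnr2 and Treml2, which B cells also express, were at low levels (Cnr2 at 6.55 and 2.31 CPM), and the B cell markers Cd79b (0.76) and Pou2af1 (1.10) were higher beside them, while Cd22 (-0.79) was lower. The B cell list's median was 1.22 in pair 1 and -0.43, -0.03 and -0.38 in the others, and CD45RBhi replicate 1 had 35 counts of Cd79a against 4 to 17 in the other memory libraries and 294 of Cd74 against 49 to 146. Cnr2, Treml2, Cd79b and Pou2af1 were nevertheless higher in CD45RBhi in 4 of 4 pairs. Cd79a counts were lower in CD45RBhi in pairs 2, 3 and 4 (4, 9 and 8 against 14, 17 and 14). Cd74 counts were lower there in pairs 2 and 4 and higher in pair 3. Whether B cells contributed to these genes was not tested. Klrg1, a receptor of terminally differentiated effector cells, was lower by the pairs (-0.52 ± 0.0606, adjusted p = 0.000703, 0.176 unpaired). So were the chemokine receptor Cx3cr1 (-0.51), the granzyme Gzma (-0.90 ± 0.102), the inhibitory receptor Pdcd1 (-0.50), and the transcription factors Zeb2 (-0.74) and Prdm1 (-0.55). Further genes with large decreases were Carns1, Plekha6, Esm1, Serpinb1a, Klra9 and Sun2. Values for Tbx21 (-0.04, adjusted p = 0.703), Eomes (0.06, 0.563), Gzmb (-0.15, 0.173), Ifng (-0.10, 0.604), Cd8b1 (0.15, 0.0752) and Cd3e (0.02, 0.853) did not pass. Of the 707 genes, 702 moved the same way in all 4 pairs, and 29 higher and 44 lower genes changed at least 2-fold. The count was 344 without pair 1, 167 without pair 3 and 300 without pair 4. With pair terms and the naive libraries kept it was 510, against a 1.5-fold change 7, and without a filter 1296. Correction for gene length and GC content moved the split by limma-trend from 331 higher and 427 lower to 524 higher and 295 lower, with 564 genes called in both, so which direction held more genes depended on it.

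**Figure D2:**
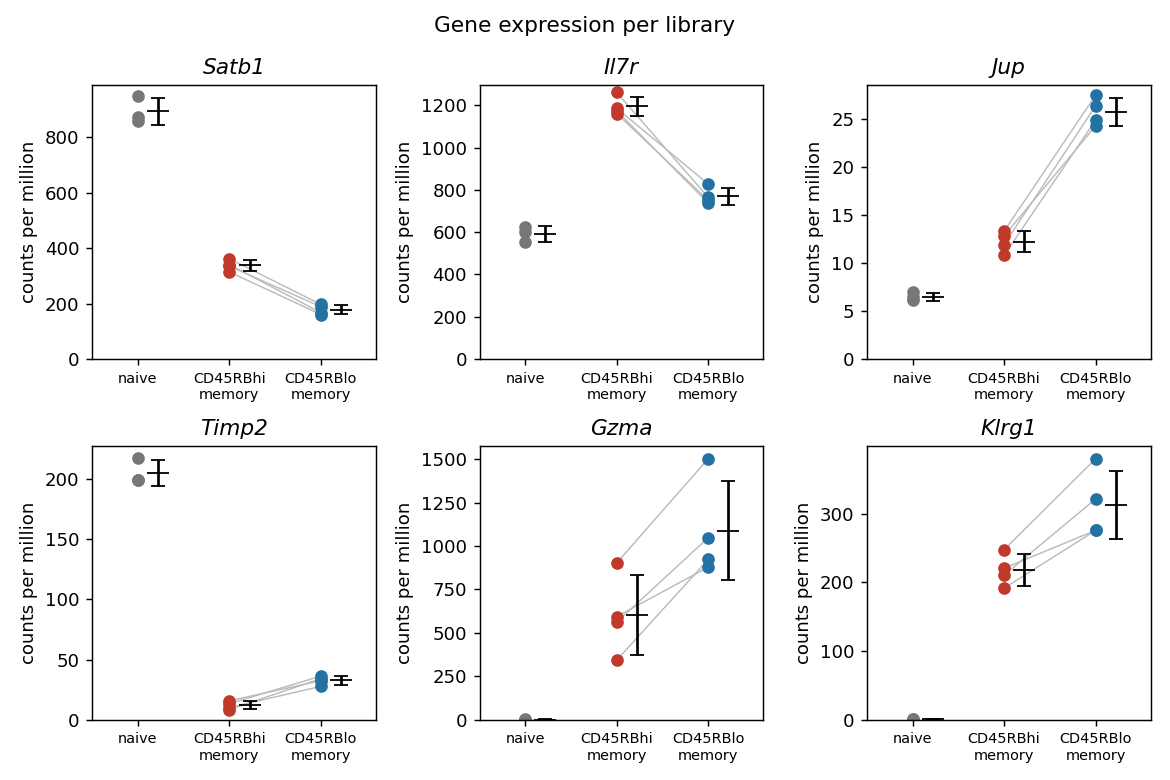
CPM per library of named genes in naive, CD45RBhi and CD45RBlo libraries, 1 point per library. Satb1 averaged 338 CPM in CD45RBhi and 178.5 in CD45RBlo libraries, and Timp2 11.9 and 32.7. In naive libraries Satb1 ran from 859.6 to 949.9 CPM and Timp2 from 198.8 to 217.1.

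Cytosolic ribosomal protein genes were higher in CD45RBhi, with a positive log2 fold change for 77 of 77 members. Of these, 2 passed over all genes and 38 when adjusted over the list alone, and with pairs 59 and 74 did, among them Rps7 (0.49) and Rpl13 (0.40). Camera gave adjusted p = 1.4e-41 (3.92e-60 paired), and adjusted p = 0.0989 with an estimated correlation (0.316 paired). Central memory and stem-like markers were higher by camera (6.23e-09, adjusted p = 0.0197 with an estimated correlation): 2 of 33 passed and 7 when adjusted over the list alone. With pairs 12 rose and 0 fell over all genes, 15 and 2 when adjusted over the list alone, and adjusted p = 0.114 with an estimated correlation. Effector differentiation markers were lower by camera (3.46e-06, adjusted p = 0.193 with an estimated correlation), with 0 of 33 passing and 9 when adjusted over the list alone. With pairs 12 fell and 1, Itgax (0.42), rose (adjusted p = 0.114 with an estimated correlation). The list of inhibitory receptors was lower (0.000935, adjusted p = 0.163 with an estimated correlation), with 6 of 21 lower and Btla (0.32) higher by the pairs. Oxidative phosphorylation genes were positive for 73 of 74 members (1.16e-12, adjusted p = 0.163 with an estimated correlation), with 4 called by the pairs, such as Ndufc2 (0.34) and Cox6c (0.29). Cell cycle genes were positive for 47 of 55 (2.42e-09, adjusted p = 0.207 with an estimated correlation), with 11 called by the pairs, such as Nusap1 (1.34) and Cdc6 (2.21) at low levels.

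Camera called further lists, with larger p, none of which was called with an estimated correlation. Tissue-residency markers (0.017, adjusted p = 0.072 with an estimated correlation) and cytokines and chemokines (0.0474, adjusted p = 0.15 with an estimated correlation) were lower in CD45RBhi. So were cytotoxic granule genes (0.0494, adjusted p = 0.404 with an estimated correlation), among which the pairs had Gzma lower, Gzmk lower (-0.32) and Gzmm higher (0.68). Markers of CD4 helper and regulatory T cells (0.0276, adjusted p = 0.218 with an estimated correlation) and of erythroid cells and platelets (0.0156, adjusted p = 0.37 with an estimated correlation) were lower too, but the erythroid list turned direction without CD45RBlo replicate 1 (mean log2 fold change 0.56, adjusted p = 0.987). By the pairs camera no longer called cytotoxic granule genes (0.0574), cytokines and chemokines (0.129) or CD4 and regulatory T cell markers (0.129). Globins and Alas2 had 437 counts in CD45RBlo replicate 1 against 5 to 31 in the other memory libraries, whereas Car2, the 1 member called by the pairs (-2.07, adjusted p = 0.00115), was lower in CD45RBhi in 4 of 4 pairs. By the pairs, erythroid and platelet markers were lower (0.00967, adjusted p = 0.316 with an estimated correlation, 3 members tested), mitochondrially encoded genes were higher (0.00967, adjusted p = 0.618 with an estimated correlation, 0 members called) and NK cell markers lower (0.0163, adjusted p = 0.473 with an estimated correlation). Adjusted p without pairs was 0.114 for NK receptors, 0.54 for homing genes, 0.763 for fatty acid oxidation, 0.0726 for glycolysis and 0.651 for receptor signalling. It was 0.538 for glycosyltransferases, 0.141 for immediate early genes, 0.657 for survival genes, 0.247 for mitochondrially encoded genes, 0.364 for B cell (0.84 by the pairs), 0.231 for macrophage and 0.0789 for dendritic cell markers. It was 0.54 for cytokine receptors, 0.54 for transcription factors, 0.845 for CD45 splicing regulators and 0.909 for interferon-stimulated genes, and in these 4 lists median, mean and test differed in sign. By the pairs, members called moved both ways among homing genes (9 higher, 5 lower of 37), transcription factors (9 and 7 of 53), interferon-stimulated genes (6 and 3 of 50) and cytokine receptors (4 and 5 of 35), where median, mean and test also differed in sign. Without pairs camera called 11 of 28 lists, 1 with an estimated correlation, and fry 6. With pairs these counts were 10, 0 and 6.

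The comparison of CD45RBhi memory with naive cells asks what separates this memory population from cells that have not met antigen. Ifng, which encodes interferon gamma, had 0 counts in naive libraries and 19.9 ± 1.81 CPM in CD45RBhi, at least 406-fold higher (3 counts over the naive group). Gzmk, a granzyme, rose from 0.114 ± 0.0296 to 233 ± 32.3 CPM, and the chemokine receptor Ccr2 from 0.416 ± 0.202 to 313 ± 75.8. S1pr5, a receptor for egress signals, rose from 0.547 ± 0.135 to 364 ± 83.2 CPM, Klrb1c from 0.313 ± 0.139 to 178 ± 52.3 and Ttc39c from 0.0958 ± 0.0427 to 82.3 ± 10.1. Klrg1 rose by 8.78, Cx3cr1 by 8.54, Gzmb by 6.66, Tbx21 by 5.80, Pdcd1 by 5.21 and Eomes by 1.96 log2 units. Igfbp4, a binding protein of insulin-like growth factors, fell from 569 ± 105 to 0.247 ± 0.138 CPM, and Ifngr2, a chain of the interferon gamma receptor, from 60.5 ± 0.293 to 0.139 ± 0.104. Ramp1 fell from 91.2 to 0.141 CPM, Chst15 from 59.6 to 0.330 and the gut homing receptor Ccr9 from 168 to 1.12. Ccr7 (-3.40) and Tcf7 (-0.67) were lower and Il7r (1.01) higher than in naive cells. In all 5694 genes passed, 3064 higher and 2630 lower, and 5408 of them did not overlap between the groups. Chance separates a given gene in this way for 1 in 35 arrangements in each direction. With library size only, which moved the median of all genes from -0.01 to -0.16, 2301 of 6025 called genes were higher and 3724 lower, so the split depended on the scaling.

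Among the lists, 32 of 33 effector differentiation markers rose in CD45RBhi (adjusted p = 0.00119 with an estimated correlation), such as S100a6 (8.90) and Osbpl3 (8.16). NK-cell receptors rose in 20 of 22, such as Klrc1 (9.01), and cytotoxic granule genes in 18 of 21, such as Fasl (0.557 to 131 CPM). Cytokines and chemokines had 8 of 16 higher and 3 lower, with Ccl5 rising from 11.9 to 4106 CPM and Ltb falling by 0.59 log2 units. Homing genes had 26 higher and 7 lower of 39, with Itgb1 (4.56) and Cxcr3 (4.56) up and Itgae (-6.00) down. Transcription factors had 26 higher and 15 lower of 54, with Bhlhe40 (8.25) up and Bach2 (-2.02) and Lef1 (1102 to 311 CPM) down. Inhibitory receptors had 15 higher and 2 lower of 21, among them Tigit (6.12) and Nr4a1 (-1.75). Survival genes had 13 higher and 4 lower of 37, and glycosyltransferases 25 higher and 6 lower of 41, with St6gal1, a sialyltransferase, falling from 176 to 3.14 CPM. These lists and the NK cell markers (11 higher, 1 lower of 15, many also expressed by memory CD8 T cells) passed with an estimated correlation. Cell cycle genes had 35 higher and 3 lower of 55 (0.000123, adjusted p = 0.381 with an estimated correlation). Oxidative phosphorylation had 41 higher and 2 lower of 74 (0.0153, adjusted p = 0.575 with an estimated correlation), and 15 and 6 with library size only. Ribosomal protein genes had 0 higher and 33 lower of 77 (0.000119, adjusted p = 0.58 with an estimated correlation), and 0 and 51 with library size only. Cytokine receptors had 18 higher and 9 lower of 36 (0.0247, adjusted p = 0.295 with an estimated correlation), with Il18rap up (5.85) and Il6st down (-3.90).

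Markers of other cells moved with this comparison. B cell markers were lower in 15 of 18 (6.16e-05, adjusted p = 0.163 with an estimated correlation) and macrophage, monocyte and neutrophil markers in 14 of 18 (0.000316, adjusted p = 0.188 with an estimated correlation). Erythroid and platelet markers were lower in 11 of 11 (3.08e-05, adjusted p = 0.193 with an estimated correlation), with Hbb-bs at 129 ± 63.0 CPM in naive and 0.353 ± 0.252 in CD45RBhi. Dendritic cell markers had 6 higher and 2 lower of 10 (0.0344, adjusted p = 0.188 with an estimated correlation). Camera called neither central memory markers (8 higher, 15 lower of 33, adjusted p = 0.0816) nor interferon-stimulated genes (9 higher, 23 lower of 52, 0.159). It called neither glycolysis (14 and 3 of 24, 0.0635) nor CD4 and regulatory T cell markers (5 and 2 of 11, 0.126) nor receptor signalling (16 and 10 of 46, 0.158). Residency (10 and 10 of 23, 0.341), splicing regulators (6 and 7 of 28, 0.651), immediate early genes (17 and 12 of 40, 0.247), fatty acid oxidation (7 and 4 of 30, 0.726) and mitochondrially encoded genes (0 of 15, 0.259) were not called. Camera called 18 of 28 lists, 10 with an estimated correlation, and fry 24. When adjusted over the list alone, central memory markers had 9 higher and 16 lower, cell cycle 41 and 3, oxidative phosphorylation 43 and 2 and transcription factors 28 and 16.

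The comparison of CD45RBlo memory with naive cells asks the same of the other memory population. Ifng was at 21.3 ± 2.49 CPM, at least 436-fold higher than in naive libraries, and Cyp17a1, a steroid hydroxylase with 0 naive counts, at 19.3 ± 8.35 CPM, at least 395-fold higher. Gzmk reached 291 ± 46.5 CPM, S1pr5 501 ± 54.2, Ttc39c 93.1 ± 4.25, Emp1 79.1 ± 17.4 (naive 0.0955 ± 0.0916) and Gzma 1088 ± 285 (naive 1.40 ± 0.411). Klrg1 rose by 9.31, Cx3cr1 by 9.03, Gzmb by 6.82, Tbx21 by 5.84, Pdcd1 by 5.71 and Eomes by 1.90 log2 units. Igfbp4 fell to 0.273 ± 0.096 CPM, Ifngr2 to 0.137 ± 0.0627, the amino acid transporter Slc6a19 from 187 ± 13.8 to 1.82 ± 1.17 and the integrin Itgae from 262 ± 30.5 to 3.85 ± 0.844. Ccr7 (-3.83) and Tcf7 (-1.02) were lower than in naive cells and Il7r (0.38) higher. In all 5794 genes passed, 3072 higher and 2722 lower, and 5584 did not overlap. With library size only, which moved the median of all genes from -0.01 to -0.14, 2356 of 5965 called genes were higher and 3609 lower.

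Of the lists, effector differentiation markers were higher in 33 of 33 (adjusted p = 0.00119 with an estimated correlation), NK-cell receptors in 20 of 22 and cytotoxic granule genes in 17 of 21. Cytokines and chemokines had 11 higher and 3 lower of 16, homing genes 27 and 8 of 39, transcription factors 29 and 14 of 54 and inhibitory receptors 16 and 2 of 21. Survival genes had 14 higher and 8 lower of 37, glycosyltransferases 24 and 7 of 41 and NK cell markers 11 and 1 of 15. All 10 of these passed with an estimated correlation. Ribosomal protein genes had 0 higher and 63 lower of 77 (2.52e-12, adjusted p = 0.332 with an estimated correlation), with Rpl3 falling by 0.95 and Rpl13 by 0.89 log2 units. Central memory markers had 10 higher and 19 lower of 33 (0.00347, adjusted p = 0.188 with an estimated correlation), with Satb1 (-2.33) and Il6st (-3.88) lower and Cd28 (1.53) higher. Cell cycle genes had 23 higher and 3 lower of 55 (0.0197, adjusted p = 0.575 with an estimated correlation). Cytokine receptors had 18 and 11 of 36 (0.0474, adjusted p = 0.332 with an estimated correlation) and CD4 and regulatory T cell markers 5 and 2 of 11 (0.0494, adjusted p = 0.215 with an estimated correlation). B cell markers were lower in 16 of 18 (4.28e-05, adjusted p = 0.188 with an estimated correlation), macrophage markers in 13 of 18 (0.00121, adjusted p = 0.215 with an estimated correlation) and erythroid markers in 11 of 11 (0.00032, adjusted p = 0.232 with an estimated correlation). Oxidative phosphorylation (15 higher and 3 lower of 74, 0.441) was not called, and its counts turned to 4 and 10 with library size only. Dendritic cell markers (5 and 2 of 10, 0.102), interferon-stimulated genes (8 and 21 of 52, 0.166), glycolysis (15 and 5 of 24, 0.158), receptor signalling (14 and 10 of 46, 0.194) and residency (11 and 7 of 23, 0.158) were not called. Neither were splicing regulators (5 and 5 of 28, 0.645), immediate early genes (18 and 11 of 40, 0.15), fatty acid oxidation (6 and 4 of 30, 0.75) and mitochondrially encoded genes (0 and 1 of 15, 0.17). Camera called 18 of 28 lists, 10 with an estimated correlation, and fry 23. When adjusted over the list alone, ribosomal protein genes had 0 higher and 67 lower, central memory markers 11 and 19 and oxidative phosphorylation 11 and 3.

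Both memory groups changed largely the same genes against naive cells. Of the tested genes, 2683 were higher in both (685 if independent), 2188 lower in both (521 if independent) and 0 were called in opposite directions. Log2 fold changes correlated at 0.967 across genes, which are not independent replicates, against 0.58 in simulated unchanged groups sharing the naive libraries. Their covariance was 2.86 against 0.0753 simulated, an excess of 2.79, and the simulated sets had 0 calls in both. The 3 naive libraries are too few to split with at least 2 on each side, so part of the excess in overlap and correlation may come from shared controls, while the covariance excess leaves out their simulated part. A call in only 1 comparison was made for 823 genes with CD45RBhi and 923 with CD45RBlo, and 3 of these were called between the memory groups.

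The naive-to-memory axis asks which memory population lies nearer to naive cells. Over the 6396 genes called between naive and the mean of both memory groups (3319 higher and 3077 lower in memory), CD45RBhi libraries lay 98.2 ± 1.71% of the way and CD45RBlo libraries 101.8 ± 2.18% (SD, n = 4 each). The scale runs from the naive mean to the mean of all memory libraries, so the values of the memory groups mirror each other by construction. The naive SD was 1.55%. The difference of -3.54 points between the memory groups gave p = 0.0286 in an exact two-sided permutation test of 70 arrangements. The exact paired test gave p = 0.125, the smallest that 4 pairs allow, with CD45RBlo further from naive in 4 of 4 pairs. CD45RBhi was nearer to naive at 55.3% of the axis genes, and at 361 of the 481 axis genes called by the pairs (75.1%), such as Satb1 and Klrg1. Other genes named between the memory groups went the other way, with CD45RBhi further from naive than CD45RBlo. Timp2 ran from 198.8 to 217.1 CPM in naive, 27.76 to 36.29 in CD45RBlo and 8.462 to 15.77 in CD45RBhi libraries. Matk ran from 48.83 to 58.54, 23.65 to 34.67 and 8.37 to 13.04 CPM, and Il7r from 551.6 to 625.7, 737.2 to 827.5 and 1161 to 1261. With axis genes changed at least 2-fold, the difference in score grew from -0.0495 to -0.0938, with an exact p of 0.0857. With library size only, 2501 of 6712 genes called between naive and memory were higher in memory and 4211 lower.

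T-cell receptor V segments were read because the memory cells were sorted for 1 epitope. Trbv17 took 19.7 ± 13.9% of Trbv counts in CD45RBhi, 16.6 ± 14.0% in CD45RBlo and 5.70 ± 0.472% in naive libraries. Its share varied by replicate number: replicate 1 lay below the naive mean in both memory groups (5.51% and 3.72%), and without replicate 3 the CD45RBlo mean was 10.7%. Trbv19 took 16.8 ± 3.82%, 14.0 ± 2.01% and 6.17 ± 0.149%, while Trbv16 took 4.44 ± 2.43%, 2.49 ± 1.16% and 13.2 ± 0.313%. Trav12-2 took 24.6 ± 6.97%, 26.3 ± 10.8% and 6.88 ± 0.799% of Trav counts. The Shannon diversity of Trbv segments was 3.11 ± 0.181 bits in CD45RBhi, 3.10 ± 0.19 in CD45RBlo and 3.97 ± 0.0106 in naive libraries. For Trav it was 4.42 ± 0.241, 4.22 ± 0.342 and 5.64 ± 0.00452 bits. Each memory group differed from naive in both diversities at p = 0.0286 in exact two-sided permutation tests of 35 arrangements, the smallest p that these allow. Adjusted over 12 tests it was 0.0572, so not past 0.05, although every memory library lay below every naive library in both diversities. Between the memory groups the exact p was 0.857 for Trbv and 0.4 for Trav diversity. Within same-numbered pairs, Trbv diversity was higher in CD45RBhi in 2 of 4 (exact paired p = 0.875) and Trav diversity in 3 of 4 (exact paired p = 0.25, where 0.125 is the smallest possible). Segments are similar in sequence, so single shares are uncertain.

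**Figure D3:**
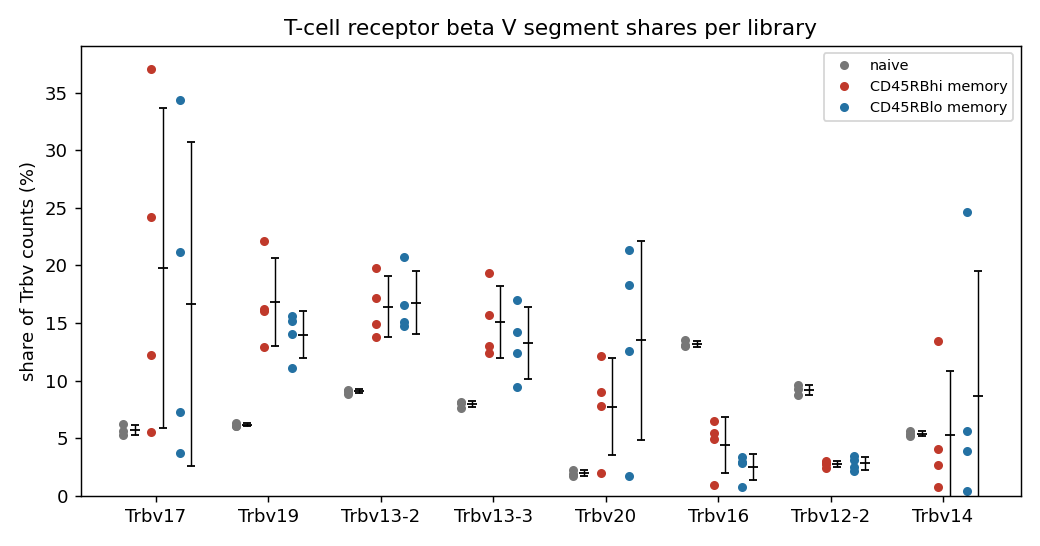
Share of Trbv counts (percent) per segment in naive, CD45RBhi and CD45RBlo libraries, with the group mean, SD bars and 1 point per library. Trbv17 and Trbv19 averaged 19.7% and 16.8% in CD45RBhi libraries and 5.70% and 6.17% in naive libraries.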

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

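Chosen only after the result was seen were the tests of naive carry-over, of scaling, of other-cell RNA in the naive libraries and of the paired arrangements, while the bounds of the tests of length and GC content and of the other splits were written before their own values were seen. The length and GC correction and the paired fit that the first of these use were themselves chosen after the data were seen. Of 266 groups of 4 values checked for a library far from the others, 22 stood out, and chance gives about 1 in 20.

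In CD45RBlo replicate 1, Hba-a1 (5.21 CPM, others at most 0.138), Hba-a2 (5.66, others at most 0.0921), Hbb-bs (9.35, others at most 0.553), Hbb-bt (3.46, others at most 0.214) and Alas2 (1.08, others at most 0.138) stood above the group. Cx3cr1 stood at 988 CPM there (others 743 to 774), Gzmm at 148 (58.9 to 71.9) and Tspan9 at 1.246 (0 to 0.0534). In CD45RBhi replicate 1, Gzmm stood at 212 CPM (103 to 114), Tspan9 at 4.26 (0 to 0.249), Tmem151a at 25.5 (15.6 to 16.5) and Tox at 91.9 (182 to 194). In CD45RBlo replicate 2, Cotl1 stood at 163 CPM (45.8 to 59.6). In CD45RBlo replicate 3, Rpl13 stood at 734 CPM (782 to 783) and Ifng at 25.04 (19.9 to 20.3). In CD45RBlo replicate 4, Hnrnpll stood at 86.6 CPM (70.1 to 72.5) and Ifngr2 at 0.23 (0.0969 to 0.113). In CD45RBhi replicate 2, Gzmk stood at 184 CPM (248 to 249), Osbpl3 at 186 (222 to 227) and the axis position at 95.7% (98.9 to 99.2). In CD45RBhi replicate 3, Car2 stood at 0.597 CPM (1.22 to 1.26), and in CD45RBhi replicate 4, Cpne7 at 6.75 (8.36 to 8.58).

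Genes higher in CD45RBhi than in CD45RBlo memory were often higher in naive cells too: 184 of the 318 (57.9%) were higher in naive than in CD45RBhi libraries, against 47.8% of all tested genes and 40.6% of the 389 lower ones. Set against CD45RBlo libraries, 230 of the 318 (72.3%) were higher in naive, with 47.7% of all tested genes and 21.1% of the lower ones. Both counts use a memory group whose values picked the genes. Naive cells carried over into CD45RBhi libraries would need a share of 37.6%, while 18 transcripts high in naive cells gave a median share of -0.069% and at most 0.00169% in a library. Correction for gene length and GC content left CD45RBhi nearer to naive at 71.2% of called axis genes (415 of 583, 75.5% before), which argues against that trend as the whole cause. A biological difference between cells sorted as CD45RBhi and CD45RBlo may remain as a hypothesis, found and tested on the same data. Reads shared between paralogs were not tested.

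Cytosolic ribosomal protein transcripts were higher in CD45RBhi memory. In 4 of 4 pairs the list's median (0.248, 0.21, 0.313 and 0.542 log2 units) lay above the central range of 1000 sets matched for length, GC content and expression, whose medians were 0.0227, 0.0804, 0.142 and 0.135. Matched genes thus moved the same way by less, and the correction lowered the list's median from 0.34 to 0.28 and its called members from 59 to 55. The matched sets hold genes drawn singly, while the list's members moved together (estimated correlation 0.694 by the pairs), so the central range may be too narrow for this list. By camera with an estimated correlation the list did not pass (adjusted p = 0.0989, 0.316 paired). Over 3 scalings and 4 pairs the smallest median was 0.206. Reads from ribosomal pseudogenes were not tested and could contribute, and a difference between the sorted populations stays open beside them.

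Erythroid, B cell and macrophage transcripts were higher in naive libraries, where 19 of the 20 most abundant members were called higher than in both memory groups. Globins and Alas2 had 11344, 4724 and 4741 counts in the naive libraries, Ighm stood at 1159 CPM against 303 and 261, and Cd74 at 61.8 against 6.47 and 5.35, while Igkc stood at 14.5 against 17.6 and 20.2. RNA or cells of other types in the naive libraries may account for these values, although the labels of the naive libraries carry the same general statement of a sort above 99% purity as those of the memory libraries. Expression in naive T cells, such as of Ighm or Ctss, and this source cannot be told apart here, because the naive sort and the naive state are the same libraries.

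For the comparisons with naive cells, no other split called as many genes as the real one, which was 1 of 35 or 1 of 100. The other splits mix naive with memory libraries, which widens the spread within groups, so few calls were likely in advance. This ranking alone therefore does not exclude chance. Between the memory groups the splits cannot exclude it either, since only 8 arrangements part all 4 pairs, too few for a share under 0.05. In the fit of the memory groups alone, which called 4 genes and not 17, the highest of 34 others called 1, and the 7 others that part all pairs called at most 0. The real split called 5429 genes between CD45RBhi memory and naive cells (highest other 0), 5906 between CD45RBlo memory and naive cells (highest other 2), and 6396 between naive and both memory groups (highest other 3 over 100 splits, drawn without regard to the pairs). In the paired fit, the real arrangement called 707 genes and the highest other 0.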

How the results depend on the processing

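The paired fits, every alternative to them, same-numbered differences in V segments, the counts of each list under each scaling and the length and GC correction were chosen after seeing the data, and the other alternatives before. Where a cause is not stated, the cause was not tested. Counts of CD45RBhi against CD45RBlo genes (17) stayed within 1.5 times with RLE (17), library size only (17), no filter (20), a 10 CPM filter (19), limma-voom (13) and the planned replicate block over all libraries (23). They were 144 with DESeq2, 0 with glmTreat at 1.5-fold, which asks for a larger change, 4 with only the groups compared, 707 with the replicate block over 8 memory libraries and 510 with the block and the naive libraries kept. Leaving out a library gave 6 to 15 genes (6 without CD45RBhi replicate 3 or 4, 9 without CD45RBlo replicate 1, 7 without CD45RBlo replicate 3 or 4). The paired count (707) was 1296 with no filter, 7 with glmTreat and 4 with no replicate block, and 167 to 667 with a pair left out (344 without 1, 167 without 3, 300 without 4). Against naive, a 10 CPM filter, which tests fewer genes, gave 3716 (CD45RBhi), 3680 (CD45RBlo) and 4146 (both) genes, with 3119 in the overlap of 4871, and glmTreat 2441, 2612 and 2760. Leaving out a library gave 4669 to 5843, 4806 to 5567 and 5282 to 6739. The planned block gave 5792, 5792 and 6457. Lists called with an estimated correlation were 1, 10 and 10 (main 11, 18 and 18) and 0 of 10 by the pairs, and fry called 6 between the memory groups with and without pairs. The erythroid and platelet list reversed between the memory groups without CD45RBlo replicate 1, the memory library with the most globin counts. Its mean log2 fold change was then 0.56 (adjusted p = 0.987), against -1.62 to -1 without any other library. The axis difference (-0.0495 in score) was -0.0938 with genes changed 2-fold (exact p = 0.0857), -0.0495 with the replicate block (exact p = 0.125, the smallest possible), and -0.0599 to -0.0376 with a library left out, where the exact p rose above 0.05 without any 1 CD45RBhi library (0.0571 to 0.0857). Fewer arrangements remained there, and the groups stayed apart (CD45RBhi at most 99.21% of the way, CD45RBlo at least 99.53%). The axis genes were kept from all libraries and not chosen anew. V segment tests lost their p with any library left out because fewer arrangements remain. Their differences from naive then ran from -0.917 to -0.776 (CD45RBhi) and -0.965 to -0.816 (CD45RBlo) bits for Trbv, from -1.32 to -1.16 and -1.55 to -1.31 bits for Trav, from 8.97 to 13.5 points for the largest Trbv share in CD45RBlo and from 14.5 to 20 for the largest Trav share in CD45RBhi. Among genes named from the paired fit, calls were lost in at least 1 fit with a pair left out for Cd44 (0.148 without 1, 0.183 without 3, 0.137 without 4), Cnr2, Treml2, Plekha6, Sun2, Cd79b, Pou2af1, Cd22, Btla, Gzmk, Ltb, Nusap1, Cdc6, Ndufc2, Cox6c, Hnrnph1, Aqp9, Il4ra, Pim2, Pmaip1, Ifi27l2a and Nfatc3. Further calls were lost with DESeq2 for Cotl1 and with the naive libraries kept for Il10ra and Ly6a. With glmTreat or without the replicate block most named genes lost their paired calls.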

Other observations

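The tests reported in this part were all chosen after the data were seen. By the pairs, members of several lists moved apart between the memory groups. The interleukin 4 receptor chain Il4ra was higher in CD45RBhi (log2 fold change 0.32, adjusted p = 0.0176), while Il18rap (-0.43) and Il10ra (-0.36) were lower. The homing receptor Gpr183 was higher (0.51, adjusted p = 0.00036) and Ccr6 lower (-2.31, adjusted p = 0.00115). Among survival genes Pim2 (0.30) was higher and Pmaip1, a pro-apoptotic factor, lower (-0.40). Among interferon-stimulated genes Usp18 (0.58) and Ly6a (0.42) were higher and Stat2 (-0.36) and Ifi27l2a (-0.36) lower. The kinase Pdk1, which restrains conversion of pyruvate to acetyl-CoA, was higher (0.41, adjusted p = 0.00422), as was Aqp9 (0.47), a glycerol channel. Plcg1 (-0.36) and Nfatc3 (-0.26) of receptor signalling were lower, and so was Hnrnph1 (-0.40) among CD45 splicing regulators.

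Same-numbered CD45RBhi and CD45RBlo libraries deviated together. A hypothesis is that they come from the same animals or pools, which the labels do not state. It was tested on V segments, since cells drawn from the same animals should share clones. Over 71 segments, deviations of shares correlated at 0.846 to 0.926 in same-numbered pairs and at -0.49 to -0.091 in others, which centring within groups of 4 pushes below 0. The mean over same-numbered pairs was 0.875, against at most 0.396 for another matching, and the exact permutation p over 24 matchings was 0.0417, the smallest they allow. The values suggest a shared source of cells, and cross-talk of indices between same-numbered libraries was not tested and stays open.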
